A study of Mus musculus with 38 samples.

How the data were processed

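RNA was sequenced from oligodendrocyte precursor cells (OPCs), the glial cells that divide and mature into myelinating oligodendrocytes. The labels describe mouse forebrain of postnatal days 6 to 7, dissociated and passed over plates that remove microglia and endothelial cells and then over a plate with an antibody against PDGFRA, a surface receptor of OPCs. Each library came from 2 pooled mice, and the labels state that both sexes were used. All mice carried floxed Bmal1 alleles. Cre-negative mice are called WT here, and mice carrying an NG2 (Cspg4) promoter Cre transgene are called KO. Cells were taken at 4 zeitgeber times (ZT) of a 12 h light and 12 h dark cycle, with ZT0 at lights on and ZT12 at lights off. The 38 libraries were poly-A selected, paired-end and made with a kit for which no strand option is stated.

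The authors deposited 1 table of raw read counts per gene, with 54532 genes and 38 sample columns. Per the submitters' processing notes, reads were processed with fastp, HISAT2 2.0.5 and featureCounts 1.5.0-p3 on the GRCm38 (mm10) mouse genome. The annotation release and the strand setting of the counting are not given in the sources used here, so reads of overlapping or near-identical genes cannot be told apart with certainty. Gene names, biotypes and coordinates are those of the deposited table. The counts are unnormalized whole numbers and were used as deposited. The total per library ranged from 19.4 to 39.0 M (mega) counts with a median of 25.9 M, and counting noise gave under 50% of the variance within groups for 22773 of the 22798 genes tested.

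Groups and replicate numbers came from the sample titles. WT had 4, 5, 6 and 4 libraries at ZT0, ZT6, ZT12 and ZT18, and KO had 4, 7, 4 and 4. No pair of libraries of a group matched within sampling noise: over 76 pairs and 14358 genes the smallest chi-square per degree of freedom was 12.21, so each library counted as 1 replicate.

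The following choices were made before the data were examined: the groups, the models, the 34 gene lists, the rule for the genes named and most of the alternatives. Genes passing filterByExpr of edgeR 4.0.16 by group were kept, which left 22798 genes holding 99.95% of all counts. TMM scaling and 1 quasi-likelihood model (glmQLFit, glmQLFTest) over the 8 groups and all 38 libraries were used, under R 4.3.3, and p-values were adjusted by Benjamini-Hochberg over the genes tested, with calls at a false discovery rate of 0.05. KO was compared with WT at each time and as the equally weighted mean of the 4 within-time differences. Dependence of the genotype difference on time, and time of day within each genotype, were tested with 3 degrees of freedom. Every p-value called adjusted for a gene came from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment unless another tool is named. Core clock genes were also fitted with a 24 h cosine per genotype, with adjustment over the 24 clock genes. CPM values are counts per M of the TMM-scaled library size, given as mean ± SD over the libraries of a group. Log2 fold changes are KO over WT with their standard error (SE).

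Gene lists were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the lists in the comparison over all times and over lists and times together for the single times. Camera was repeated with the correlation estimated from the libraries, and its p is given unadjusted and then adjusted. List members past the threshold were counted over all genes tested and again with p-values adjusted over the list alone. For tests of time and of the interaction, the share of called list members was compared with that of the other tested genes by a one-sided Fisher's exact test, adjusted over lists. This test treats genes as independent, whereas genes of a list vary together, with an estimated correlation of 0.446 for immediate early genes. Its p-values may therefore be too small, and no version that allows for correlation was run. The core clock list and the list of direct BMAL1 target genes share 13 genes and are not independent. Lists of microglia, endothelial, mural, astrocyte, neuron, choroid plexus and red blood cell markers served to follow other cells, and the list of sex-linked genes to follow the sex of the mice.

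Genes were named by a fixed rule: Arntl, the mouse symbol of Bmal1; the core clock genes; the 10 largest called changes in each direction over all times with mean log2 CPM above 1 and the same sign at all 4 times; the 5 largest in each direction at each time; the 10 smallest p-values of each test without a direction; and up to 4 members of every list. Unnamed gene models, pseudogenes and sex-linked genes were skipped. Any other gene named was chosen after its values were seen, which holds for Ajap1, Dmp1, Gm43481, Gm47237, Gm47980, Odf3l1, Lingo1, Snupn, Ptpn9, Cspg4, Pea15a, Ackr1 and the Ifi200 family.

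The model was tested on simulated counts drawn from the real means, dispersions and library sizes, with 200 genes changed by known folds among 22798 genes. The changed genes were drawn from those with mean log2 CPM above 1. Genes were simulated independently and without uneven sets of libraries, so the recovery does not cover weaker genes or such sets. For the comparison over all times it recovered 88.1% of genes changed 1.5-fold and 100% of those changed 2-fold or 4-fold. At ZT12 it recovered 56.7%, 79.1% and 97.0% of genes changed 1.5-fold, 2-fold and 4-fold, and for the interaction 22.4%, 62.7% and 90.9%.

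Alternatives covered DESeq2 1.42.0, limma-voom with sample weights, other scalings (DESeq2's size factors, abbreviated RLE, and library size alone), other count filters, surrogate variables from sva 3.50.0, a covariate for male RNA, a replicate block, fits of fewer groups, and every library left out in turn. After the data were seen, 5 more were added: leaving out 8 libraries with a low ribosomal RNA share, a term for these libraries, a correction for GC content and length of transcripts, leaving out KO ZT6 libraries 6 and 7, and leaving out libraries of a single sex. The levels of gene lists without these libraries and between low-rRNA and other libraries, and the share of counting noise, were also computed only then. Without the 8 low-rRNA libraries no KO ZT18 library is left, so values over all times from that fit average ZT0, ZT6 and ZT12 only. At ZT18 the set coincides with genotype. The term for it was thus estimated within WT ZT12 and KO ZT6 alone and carried over to ZT18, where it cannot separate set from genotype. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15, with pandas 2.3.3 and numpy 2.4.6.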

Results

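The data were raw read counts per gene in 38 libraries of mouse OPCs, of which 19 were WT and 19 were labelled as lacking functional BMAL1 (KO), a transcription factor that drives the circadian clock. WT libraries numbered 4, 5, 6 and 4 at ZT0, ZT6, ZT12 and ZT18, and KO libraries 4, 7, 4 and 4. Totals ranged from 19.4 to 39.0 M counts per library, with a median of 25.9 M. The share of counts in ribosomal RNA genes split the libraries, with 8 at or below 0.263% and 30 at or above 0.409%. These 8 low-rRNA libraries were WT ZT12 replicates 4, 5 and 6, KO ZT6 replicate 7 and all 4 KO ZT18 replicates, and they averaged 32.6 M counts against 24.9 M in the other 30. At ZT18 this split therefore coincided with genotype. Xist and Y-linked genes showed RNA of 1 sex in 13 libraries, 7 female and 6 male. Of these, 4 of the 6 WT ZT12 libraries were female, 3 of the 7 KO ZT6 libraries were male, and none of the KO ZT12 libraries was single-sex. Microglia and macrophage markers averaged 7.84 to 8.60 log2 CPM by group, close to OPC markers at 8.71 to 8.92. The libraries thus held RNA of microglia as well, and a change in a gene cannot be assigned to OPCs from these counts alone.

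Arntl (ENSMUSG00000055116, chromosome 7, 113207465 to 113314126), the gene that encodes BMAL1, was counted at similar levels in both genotypes. In WT it averaged 24.2 ± 6.16 (SD, n = 4), 20.6 ± 0.818 (n = 5), 22.8 ± 2.68 (n = 6) and 25.6 ± 4.19 (n = 4) CPM at ZT0, ZT6, ZT12 and ZT18. In KO it averaged 20.8 ± 2.56 (n = 4), 20.8 ± 1.93 (n = 7), 22.1 ± 1.18 (n = 4) and 19.2 ± 1.5 (n = 4) CPM. Single WT libraries lay between 19.4 and 33.2 CPM, and single KO libraries between 17.7 and 23.4 CPM. The log2 fold change of Arntl over all times was -0.17 (adjusted p = 0.183), and at ZT18 it was -0.42 (adjusted p = 0.0741). Cre removes only the part of Arntl that encodes the DNA-binding domain, per the labels, and the count per gene includes the exons that remain, so these values do not check the genotype labels.

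The comparison of KO with WT over all times asks which genes differ between Cre carriers and Cre-negative mice, whatever the hour. No Cre-positive group with intact Bmal1 exists, so loss of BMAL1 and effects of the transgene are not separated. Per3 and Nr1d2, a period repressor and a nuclear receptor that represses Arntl, were both lower in KO, and Cry1, a cryptochrome repressor of the clock, was higher. Per3 (chromosome 4, 151003652 to 151044665) had a log2 fold change of -0.72 (SE 0.0822, adjusted p = 1.09e-06), with 12 of 19 KO libraries below every WT library. It averaged 50.8 ± 15.4 (SD, n = 4), 52.5 ± 7.38 (n = 5), 42.2 ± 6.61 (n = 6) and 51.5 ± 6.16 (n = 4) CPM in WT, against 25.6 ± 2.48 (n = 4), 30 ± 6.87 (n = 7), 35.7 ± 2.28 (n = 4) and 28.8 ± 3.84 (n = 4) CPM in KO. Nr1d2 (chromosome 14, 18204054 to 18239127) had -0.55 (SE 0.0735, adjusted p = 2.43e-05), with 15 KO libraries below every WT library. Cry1 (chromosome 10, 85131700 to 85185064) had 0.35 (SE 0.0704, adjusted p = 0.0275). Among the 24 core clock genes 1 rose and 2 fell, and adjusted over the list alone 1 rose and 6 fell. Camera called the list lower (adjusted p = 0.00963), with p = 0.0948 with an estimated correlation (0.403 adjusted). No gene list in any comparison passed once its p with an estimated correlation was adjusted, and the lowest such value was 0.0729, for glycolysis at ZT18. Among 20 direct BMAL1 target genes the median was 0.01 and the mean -0.06, and the test pointed down without passing (adjusted p = 0.0642), although it passed without the 8 low-rRNA libraries (adjusted p = 0.000919, with ZT18 left out). It also passed without WT ZT0 replicate 1, WT ZT6 replicate 5, WT ZT12 replicate 1, WT ZT18 replicate 3, KO ZT0 replicate 3, KO ZT6 replicate 1, 2, 3 or 4, KO ZT12 replicate 3 or KO ZT18 replicate 4 (adjusted p from 0.00586 to 0.0499). Per3 and Nr1d2 passed without the 8 low-rRNA libraries (-0.72 and -0.60), whereas Cry1 did not (adjusted p = 0.368), nor in 8 of the 38 fits that left out 1 library.

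**Figure D1:**
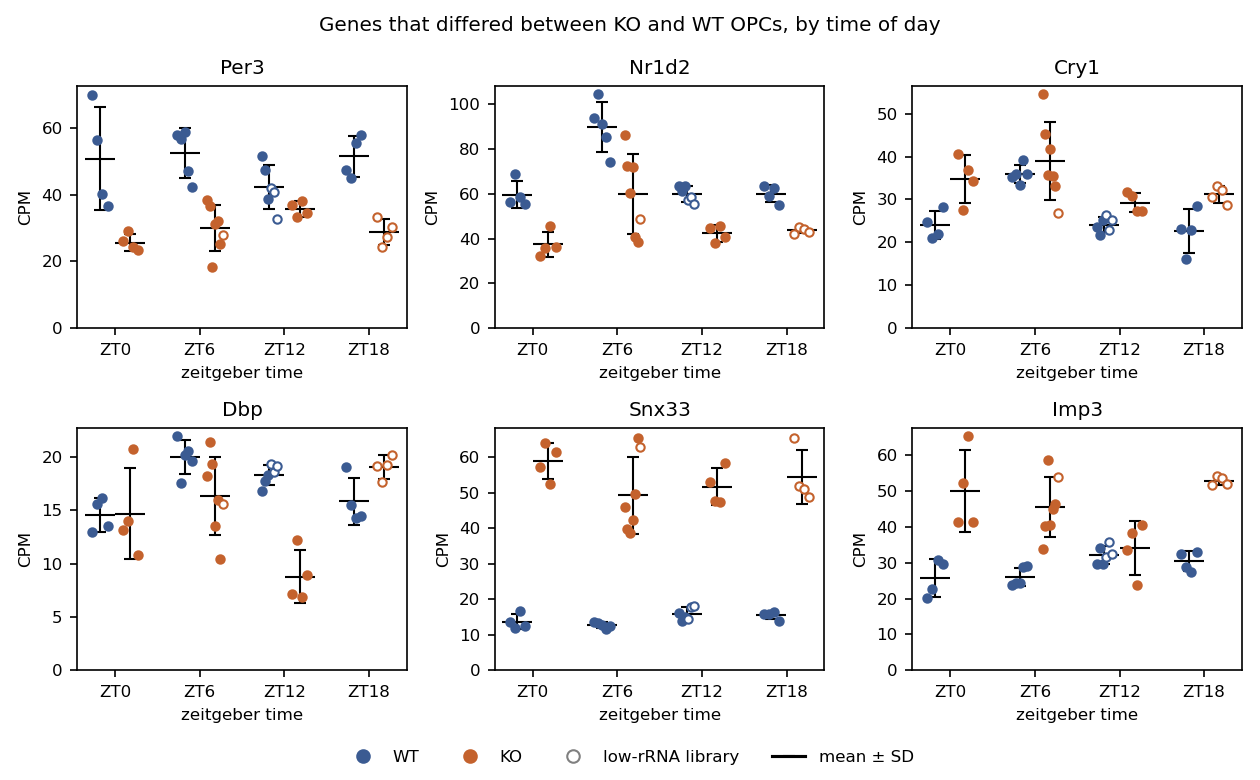
CPM of 6 genes (y axis) in each library by zeitgeber time (x axis) and genotype, with points for libraries (open for the low-rRNA set) and bars for the mean ± SD. All 19 KO libraries lay above every WT library for Snx33, and 15 lay below every WT library for Nr1d2.

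The smallest p-value over all times was that of Snx33, a sorting nexin that shapes membranes in endocytosis. Snx33 (ENSMUSG00000032733, chromosome 9, 56917193 to 56928371) was 3.72-fold higher in KO (log2 1.90, SE 0.0664, adjusted p = 1.66e-22), with all 19 KO libraries above every WT library. It averaged 12.7 ± 0.763 CPM (SD, n = 5) in WT and 49.3 ± 10.9 CPM (n = 7) in KO at ZT6, and its interaction with time did not pass (adjusted p = 0.393). Its neighbour Imp3, a protein of ribosomal RNA processing (chromosome 9, 56937475 to 56938398), rose by 0.66 (SE 0.0728, adjusted p = 6.57e-07), and Gm47237 between Snx33 and Cspg4 by 1.43 (SE 0.301, adjusted p = 0.0381). Cspg4, whose promoter drives the Cre transgene, starts at 56865033 on the same chromosome. It had a log2 fold change of -0.13 (SE 0.073, adjusted p = 0.385), and Odf3l1 on its other side had 1.41 (SE 0.397, adjusted p = 0.112). On chromosome 1, Tagln2, an actin-binding protein, rose by 0.48 (SE 0.0631, adjusted p = 2.18e-05) and Cadm3, a cell adhesion molecule, by 0.37 (SE 0.0542, adjusted p = 0.000163). Mndal, an interferon-inducible gene of the Ifi200 family at 173849126 to 173942491 on that chromosome, had -0.99 (SE 0.167, adjusted p = 0.00278). All 12 genes measured at that locus, Aim2 included, had negative fold changes, from -0.11 for Aim2 to -1.06 for Ifi205, and Mndal alone passed the test. Cadm3 and Mndal did not pass without the 8 low-rRNA libraries (adjusted p = 0.126 and 0.28). Reads of the similar genes of this family cannot be fully told apart.

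**Figure D2:**
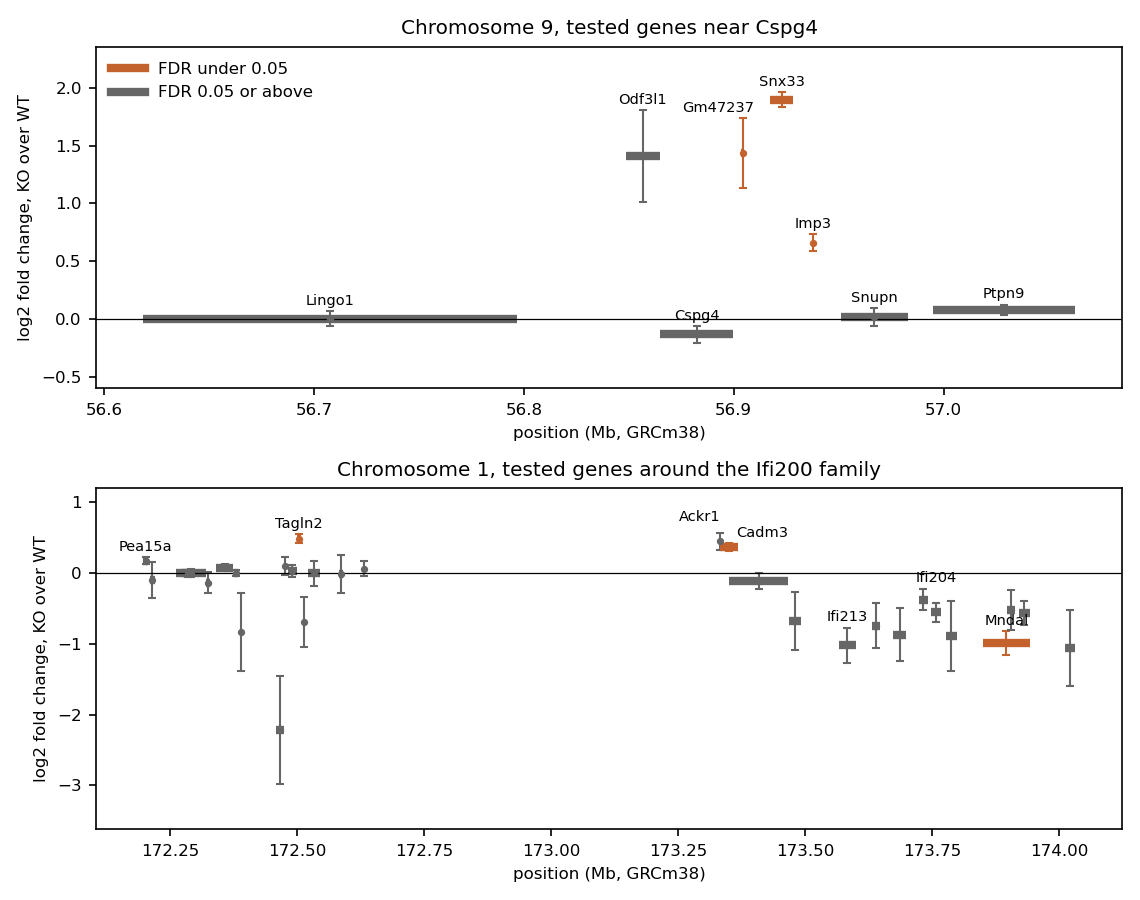
Log2 fold change of KO over WT over all times (y axis, bars ± SE) by position (x axis) for the tested genes near Cspg4 on chromosome 9 and around the Ifi200 family on chromosome 1, with orange for genes that passed the test. Snx33 stood highest near Cspg4 at 1.90, and Mndal passed among the genes of the Ifi200 family at -0.99.

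Genes of energy metabolism and translation were higher in KO averaged over all times, but not at ZT12. All 24 oxidative phosphorylation genes had positive fold changes (median 0.19). Ndufa1 of complex I rose by 0.41 (SE 0.0823, adjusted p = 0.0241) and Cycs, the electron carrier cytochrome c, by 0.28 (SE 0.0594, adjusted p = 0.0405), while adjusted over the list alone all 24 rose. Camera called the list higher (adjusted p = 2.38e-20), with p = 0.00639 with an estimated correlation (0.141 adjusted). All 24 ribosomal protein genes were also positive (median 0.20), with 0 called over all genes, 20 adjusted over the list alone, and an adjusted p of 6.07e-18, or p = 0.0249 with an estimated correlation (0.141 adjusted). At ZT12 16 of 24 oxidative phosphorylation genes were negative (median -0.06, adjusted p = 0.348) and 12 of 24 ribosomal protein genes (median -0.02, adjusted p = 0.864; 0.01 and 0.03 with RLE scaling and library size alone). Glycolysis genes were lower there as a list (18 of 21 negative, median -0.19, adjusted p = 0.0119, p = 0.0655 with an estimated correlation, 0.443 adjusted), with 1 called over all genes and 1 adjusted over the list alone, and did not pass without the 8 low-rRNA libraries (adjusted p = 0.0758). Single genes that rose included Ppia, a prolyl isomerase (0.38, adjusted p = 0.0143), Magohb of the exon junction complex (0.39, adjusted p = 0.0163), Snrpf of the spliceosome (0.40, adjusted p = 0.0346), Dbi, which binds acyl-CoA (0.31, adjusted p = 0.0401), and Sae1 of SUMO activation (0.21, adjusted p = 0.0393). Rbm48 fell by 0.39 (adjusted p = 0.0393). Red blood cell markers moved with these groups (9 of 9 positive, median 0.36, adjusted p = 2.31e-06), as did neuron markers (18 of 20, median 0.19, adjusted p = 4.9e-05), with p = 0.0214 and 0.151 with an estimated correlation (0.141 and 0.513 adjusted). Without the 8 low-rRNA libraries the oxidative phosphorylation and ribosomal protein lists passed (adjusted p = 1.32e-11 and 1.27e-10), whereas red blood cell and neuron markers did not (adjusted p = 0.341 each). That fit leaves out ZT18, where red blood cell and neuron markers had their largest medians (0.86 and 0.57). Calls lost in it may therefore reflect the missing time as well as the set. The median of the neuron markers was 0.12 without KO ZT6 replicate 4 and 0.10 without KO ZT12 replicate 4. edgeR's quasi-likelihood test called 21 of 22798 genes, 15 higher and 6 lower. The remaining 4 were Ajap1 (0.43), Dmp1 (2.78), Gm43481 (-0.55) and Gm47980 (-2.92). DESeq2 called 244 and limma-voom 1056, but 5 genes passed without the 8 low-rRNA libraries (Snx33, Imp3, Tagln2, Per3 and Nr1d2) and 8 without the single-sex libraries. The count was 633 without WT ZT0 replicate 4, 38 without KO ZT0 replicate 4, 35 without KO ZT6 replicate 1, 10 without KO ZT0 replicate 3, 12 without WT ZT0 replicate 3 or WT ZT18 replicate 2, and 13 without WT ZT0 replicate 1 or 2, KO ZT0 replicate 1 or KO ZT18 replicate 3. The calls of Snrpf, Dbi, Sae1 and Rbm48 were lost in 16, 23, 27 and 22 of the 38 fits that left out 1 library.

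At ZT0 cholesterol and energy lists rose in KO, but chance is not excluded for the gene count. Per3 fell by 0.99 (SE 0.176, adjusted p = 0.0121) and Nr1d2 by 0.67 (SE 0.157, adjusted p = 0.0483). Snx33 rose by 2.11 (SE 0.143, adjusted p = 9.16e-13), Imp3 by 0.96 (SE 0.156, adjusted p = 0.00464) and Ndufa1 by 0.95 (SE 0.177, adjusted p = 0.0173). Atp5k, a subunit of ATP synthase, rose by 1.32 (SE 0.303, adjusted p = 0.0464) and Irx3, a homeobox factor, by 1.32 (SE 0.305, adjusted p = 0.0464). Mir142hg, host of a microRNA of blood cells, had -1.60 (SE 0.37, adjusted p = 0.0464), the inflammasome sensor Nlrp1b -1.52 (SE 0.333, adjusted p = 0.0453) and Unc13d, which acts in granule release, -1.32 (SE 0.292, adjusted p = 0.0453). Of 24 cholesterol biosynthesis genes 23 were positive (median 0.41), with 0 called over all genes and 12 adjusted over the list alone. The list passed camera (adjusted p = 6.06e-10), with p = 0.0352 with an estimated correlation (0.368 adjusted), and Hmgcs1, an early enzyme of the pathway, had 0.57 (adjusted p = 0.0721). Oxidative phosphorylation genes rose as a list (median 0.36, adjusted p = 2.82e-15, p = 0.0147 with an estimated correlation, 0.368 adjusted), with 1 called and 22 adjusted over the list alone. All 20 microglia markers were negative (median -0.36, adjusted p = 0.00261, p = 0.374 with an estimated correlation, 0.778 adjusted), with 0 called over all genes or adjusted over the list alone. The microglia list did not pass without WT ZT0 replicate 3 or KO ZT0 replicate 1 (adjusted p = 0.233 and 0.261). Neuron markers (17 of 20 positive, median 0.22, adjusted p = 0.0153), choroid plexus markers (12 of 12, median 0.67, adjusted p = 0.0304) and OPC markers (17 of 20, median 0.15, adjusted p = 0.0143) were higher as lists, with p = 0.363, 0.127 and 0.31 with an estimated correlation (0.772, 0.54 and 0.743 adjusted). None of these genes was called over all genes. Adjusted over the list alone 0, 0 and 1 were. The neuron list did not pass without WT ZT0 replicate 1 or 3 or KO ZT0 replicate 1 (adjusted p = 0.0927, 0.22 and 0.0785). Its median was 0.44 without WT ZT0 replicate 2. The choroid plexus list did not pass without WT ZT0 replicate 3 or KO ZT0 replicate 2 or 3 (adjusted p = 0.0616, 0.0597 and 0.141). The OPC list did not pass without WT ZT0 replicate 2 or KO ZT0 replicate 1 (adjusted p = 0.105 and 0.0997). edgeR called 65 genes, 42 higher and 23 lower, against 38 and 54 with RLE scaling and 44 and 45 with library size alone. The count was 4 without the 8 low-rRNA libraries and 1 without the single-sex libraries. It also turned on single libraries: 2208 without WT ZT0 replicate 4, 487 without KO ZT0 replicate 4 and 417 without KO ZT6 replicate 3, but 1 without WT ZT0 replicate 2 or KO ZT0 replicate 3, 4 without WT ZT0 replicate 3, 5 without WT ZT0 replicate 1 and 7 without KO ZT0 replicate 1. It was 15 without KO ZT0 replicate 2, 12, 43, 18, 18 and 42 without WT ZT6 replicates 1 to 5, and 17, 28 and 39 without KO ZT6 replicates 4, 5 and 6. It was 106, 15, 22 and 14 without WT ZT12 replicates 1, 4, 5 and 6, 42 and 14 without KO ZT12 replicates 1 and 2, 12 without WT ZT18 replicate 1, 2 or 3, and 11, 12, 13 and 11 without KO ZT18 replicates 1 to 4. Per3 did not pass without WT ZT0 replicate 1 or 2 or KO ZT0 replicate 3 (-0.80, -0.94 and -0.96), and Imp3 not without WT ZT0 replicate 2 or KO ZT0 replicate 3 (0.89 and 0.80).

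At ZT6, the middle of the light phase, the genotypes differed in few genes. Snx33 rose by 1.96 (SE 0.122, adjusted p = 6.41e-14), Imp3 by 0.81 (SE 0.131, adjusted p = 0.00423), and Per3 fell by 0.81 (SE 0.143, adjusted p = 0.0136). Of the 24 core clock genes 20 were negative (median -0.14), among them Nr1d1, the partner of Nr1d2, at -0.55 (SE 0.214, adjusted p = 0.974). Camera called the list lower (adjusted p = 4.61e-06), with p = 0.00508 with an estimated correlation (0.346 adjusted), and 1 gene fell over all genes and 2 adjusted over the list alone. Direct BMAL1 target genes were also lower as a list (median -0.06, adjusted p = 0.000339, p = 0.0298 with an estimated correlation, 0.368 adjusted), with 1 gene called over all genes and 2 adjusted over the list alone. Microglia markers were all positive (20 of 20, median 0.28, adjusted p = 0.000144), with p = 0.267 with an estimated correlation (0.727 adjusted). Astrocyte markers were also higher (16 of 18, median 0.17, adjusted p = 0.0221), with p = 0.327 with an estimated correlation (0.743 adjusted) and 0 called over all genes or adjusted over the list alone. That list did not pass without WT ZT6 replicate 1, 2 or 4 (adjusted p = 0.246, 0.0545 and 0.168) or KO ZT6 replicate 2, 5, 6 or 7 (adjusted p = 0.114, 0.0881, 0.0966 and 0.0592). The astrocyte median was 0.40 without WT ZT6 replicate 3 and 0.28 without KO ZT6 replicate 1. Without KO ZT6 replicates 6 and 7 the BMAL1 target list did not pass (median 0.01, adjusted p = 0.243), nor did it without the single-sex libraries (adjusted p = 0.152). The mean log2 CPM of that list differed by -0.207 (SE 0.11) with all libraries and by -0.0532 (SE 0.0652) without replicates 6 and 7. For the core clock list this difference was -0.268 (SE 0.101) and -0.158 (SE 0.0951), and camera passed without the 2 replicates (median -0.07, adjusted p = 0.00509). The clock median was -0.0863 without KO ZT6 replicate 7 and -0.205 without replicate 4, and the microglia median 0.157 without replicate 3. edgeR called 3 genes of 22798, limma-voom 5 and DESeq2 3, and 1000 had an unadjusted p under 0.05. The count was 5 without KO ZT6 replicate 1, and without the 8 low-rRNA libraries or the single-sex libraries Snx33 alone passed.

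At ZT12, lights off, KO libraries had less transcript of immediate early genes, the first genes transcribed after a stimulus, with much of the difference in the low-rRNA WT libraries. All 22 were negative (median -0.86), 9 fell over all genes and 20 adjusted over the list alone. Klf2 had -1.41 (SE 0.298, adjusted p = 0.00515), from 261 ± 108 (SD, n = 6) to 98.2 ± 24.8 CPM (n = 4), and Atf3, a stress-responsive factor, had -1.12 (SE 0.313, adjusted p = 0.0314). Egr4, an early growth response factor outside that list, had -1.83 (SE 0.381, adjusted p = 0.00478). The list passed camera (adjusted p = 3.89e-12), with p = 0.0158 with an estimated correlation (0.368 adjusted). Without the 8 low-rRNA libraries, 3 of which are WT ZT12 libraries, it passed with a smaller median (-0.43, adjusted p = 0.000147), and the difference in its mean log2 CPM went from -0.812 (SE 0.232) to -0.413 (SE 0.228). On that scale the low-rRNA WT libraries stood at 8.24 to 8.38 and the other WT libraries at 7.21 to 7.86. KO libraries stood at 6.74 to 7.26. Dbp, a clock output factor and BMAL1 target, fell by 1.06 (SE 0.167, adjusted p = 0.000491), from 18.3 ± 0.929 (SD, n = 6) to 8.78 ± 2.45 CPM (n = 4). Nr1d1 had -0.81 (adjusted p = 0.0472), Nr1d2 -0.50 (adjusted p = 0.0357) and Clock, the partner of BMAL1, 0.40 (adjusted p = 0.045). These calls were lost in 34, 13 and 26 of 53 alternative fits, and that of Dbp in 1. Of 20 direct BMAL1 target genes 19 were negative, 4 fell over all genes and 5 adjusted over the list alone (list adjusted p = 0.000677, p = 0.0387 with an estimated correlation, 0.376 adjusted).

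OPC markers were lower as a list at ZT12 (median -0.27, adjusted p = 0.014, p = 0.307 with an estimated correlation, 0.743 adjusted), with 3 of 20 lower over all genes and, adjusted over the list alone, 8 lower and 1 higher. Among them C1ql1, a secreted C1q-like protein, had -1.03 (SE 0.169, adjusted p = 0.000774) and Neu4, a sialidase, -0.74 (SE 0.208, adjusted p = 0.0316). Markers of committed precursors also fell as a list (median -0.13, adjusted p = 0.0411, p = 0.0861 with an estimated correlation, 0.491 adjusted), with 2 of 14 called and 4 adjusted over the list alone, and Bmp4, a differentiation-blocking growth factor, had -0.97 (SE 0.262, adjusted p = 0.0251). Hic1, a transcriptional repressor, had -1.80 (SE 0.424, adjusted p = 0.011), Clec3b, or tetranectin, -2.19 (SE 0.653, adjusted p = 0.0433), and Ndufa4l2, a mitochondrial protein induced by hypoxia, -2.09 (SE 0.641, adjusted p = 0.0488). The calls of Hic1, Clec3b and Ndufa4l2 were lost in 9, 18 and 42 of 53 alternative fits. Snx33 rose by 1.70 (SE 0.124, adjusted p = 8.25e-12), the clotting factor F9 by 1.09 (SE 0.323, adjusted p = 0.0416), the scramblase Plscr4 by 0.96 (SE 0.28, adjusted p = 0.038), Zc2hc1c by 1.12 (adjusted p = 0.0312) and Srp54b of the signal recognition particle, which has near-identical copies, by 1.94 (SE 0.584, adjusted p = 0.045). CAAA01147332.1, on an unplaced scaffold, fell by 2.49 (adjusted p = 0.00617). Mural and fibroblast markers moved with these genes (18 of 19 negative, median -0.86, adjusted p = 0.00557, p = 0.18 with an estimated correlation, 0.644 adjusted), with 2 called over all genes and 4 adjusted over the list alone. The OPC list did not pass without KO ZT12 replicate 3 (adjusted p = 0.0832), the committed precursor list not without WT ZT12 replicate 3 or KO ZT12 replicate 2 or 3 (adjusted p = 0.139, 0.14 and 0.0822), and the mural list not without WT ZT12 replicate 5 (median -0.37, adjusted p = 0.057). Sex-linked genes also differed (5 of 6 positive, adjusted p = 0.00255, p = 0.028 with an estimated correlation, 0.368 adjusted). edgeR called 1139 genes, 298 higher and 841 lower, against 376 and 708 with RLE scaling and 424 and 578 with library size alone. With a term for the low-rRNA libraries 78 passed, without these libraries Snx33 alone passed, and with a correction for GC content and length 122 passed, 60 higher and 62 lower. The count was 259 without KO ZT12 replicate 1 or 3, and 562, 654 and 621 without WT ZT12 replicates 4, 5 and 6.

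At ZT18, in the dark phase, KO libraries had more myelin and stress transcripts. Mbp, or myelin basic protein, rose by 1.25 (SE 0.231, adjusted p = 0.00866), from 80.4 ± 2.89 (SD, n = 4) to 191 ± 43.9 CPM (n = 4). Cldn11, a tight junction protein of myelin, rose by 1.22 (SE 0.265, adjusted p = 0.0157), Adamts4, a protease of mature oligodendrocytes, by 1.24 (SE 0.266, adjusted p = 0.0149), and Cnp, an enzyme of the myelin membrane, by 0.48 (SE 0.113, adjusted p = 0.0223). Of 23 myelin genes 19 were positive (median 0.48), 5 rose over all genes and 7 adjusted over the list alone, and the list passed (adjusted p = 0.000242, p = 0.0245 with an estimated correlation, 0.368 adjusted). OPC markers were lower (median -0.11, adjusted p = 0.0274, p = 0.363 with an estimated correlation, 0.772 adjusted), with 0 of 20 called and 5 adjusted over the list alone. The chaperone genes Hspa1a and Hspa1b, whose reads are hard to separate, rose by 5.36 (SE 1.29, adjusted p = 0.0244) and 7.50 (adjusted p = 0.0352), Hspa1a from 3.49 ± 0.692 (SD, n = 4) to 143 ± 61.6 CPM (n = 4). The stress cytokine Gdf15 rose by 4.56 (SE 1.09, adjusted p = 0.0239), and Il1b and Cd83, an inflammatory cytokine and an activation marker of immune cells, by 4.08 (SE 0.941, adjusted p = 0.0205) and 3.11 (SE 0.715, adjusted p = 0.0203). Microglia markers averaged 8.60 log2 CPM in KO and 8.26 in WT at this time, so whether these transcripts came from OPCs or microglia is not known. Of 22 immediate early genes 17 were positive (median 0.66), with 6 called and 10 adjusted over the list alone (list adjusted p = 6.13e-07, p = 0.0683 with an estimated correlation, 0.443 adjusted). The immediate early list had a median of -0.03 with a term for the low-rRNA set (adjusted p = 0.919), and within WT ZT12, where genotype plays no part, its mean log2 CPM was higher in low-rRNA than in other libraries by 0.799 (SE 0.2), against 0.659 (SE 0.162) between KO and WT at ZT18. The list median was 0.43 without KO ZT18 replicate 4. Heat shock genes were higher as a list at ZT18 (13 of 16 positive, median 0.30, adjusted p = 0.00194, p = 0.197 with an estimated correlation, 0.649 adjusted). Of these genes 2 were called over all genes, and 5 rose and 1 fell adjusted over the list alone. Their mean log2 CPM differed by 0.00967 (SE 0.372) within WT ZT12 and by 1.09 (SE 0.0808) at ZT18. That mean includes the large folds of Hspa1a and Hspa1b. The OPC list did not pass without WT ZT18 replicate 2 or KO ZT18 replicate 2 or 4 (adjusted p = 0.164, 0.0888 and 0.133).

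Glycolysis genes rose as a list at ZT18 (19 of 21 positive, median 0.34, adjusted p = 5.83e-08, p = 0.000536 with an estimated correlation, 0.0729 adjusted), with 5 called and 12 adjusted over the list alone. Among them the glycolytic enzymes Aldoa and Pgk1 rose by 0.55 (SE 0.124, adjusted p = 0.0189) and 0.40 (SE 0.107, adjusted p = 0.0427). All 24 ribosomal protein genes were positive (median 0.36, adjusted p = 4.22e-12, p = 0.0586 with an estimated correlation, 0.433 adjusted), with 3 called and 17 adjusted over the list alone. Within WT ZT12 the low-rRNA libraries were higher than the others by 0.102 (SE 0.0199) in mean log2 CPM of the glycolysis list and by 0.184 (SE 0.0494) of the ribosomal protein list. The differences between KO and WT at ZT18 were 0.335 (SE 0.0377) and 0.435 (SE 0.0939). The 2 lists passed with a term for this set, with smaller medians (0.19 and 0.22, adjusted p = 2.2e-05 and 1.72e-05). That term was estimated within WT ZT12 and KO ZT6, so it cannot separate the set from genotype at ZT18. In the clock, Per3 fell by 0.84 (SE 0.175, adjusted p = 0.0127), while Nfil3, a repressor that opposes Dbp, rose by 1.10 (SE 0.307, adjusted p = 0.0488) and Bhlhe41, a repressor of BMAL1 targets, by 0.97 (SE 0.263, adjusted p = 0.0427). The calls of Per3, Nfil3 and Bhlhe41 were lost in 5, 34 and 15 of 52 alternative fits. Direct BMAL1 target genes, lower as a list at ZT6 and ZT12, were higher at ZT18 (15 of 20 positive, median 0.19, adjusted p = 0.0464, p = 0.2 with an estimated correlation, 0.649 adjusted). Over all genes 1 rose and 1 fell, and adjusted over the list alone 7 rose and 2 fell. This call was lost without the single-sex libraries (adjusted p = 0.0612). It was also lost without WT ZT0 replicate 1, WT ZT6 replicate 5, WT ZT18 replicate 1, 2 or 3, KO ZT6 replicate 3 or 5 or KO ZT18 replicate 4 (adjusted p from 0.0502 to 0.0734). Malat1, a nuclear noncoding RNA, had -1.28 (SE 0.348, adjusted p = 0.0443), Lars2, the mitochondrial leucyl-tRNA synthetase, -2.48 (SE 0.588, adjusted p = 0.0224), Mtcp1 -1.15 (adjusted p = 0.0188) and the zinc finger gene Zfp975 -1.09 (adjusted p = 0.0149). CT010467.1 had -2.51 (adjusted p = 0.022) and is itself a ribosomal RNA gene. Ribosomal RNA took 0.154% of counts in KO and 0.907% in WT at this time. Markers of other cells moved with these groups: endothelial markers (16 of 16 positive, median 0.63, adjusted p = 0.00216), neuron markers (18 of 20, median 0.57, adjusted p = 0.000268) and red blood cell markers (9 of 9, median 0.86, adjusted p = 4.61e-06), with p = 0.174, 0.187 and 0.0242 with an estimated correlation (0.644, 0.649 and 0.368 adjusted). Microglia markers (16 of 20, median 0.31, adjusted p = 0.0189) and mural and fibroblast markers (15 of 19, median 0.42, adjusted p = 0.0202) were also higher, with p = 0.478 and 0.255 with an estimated correlation (0.871 and 0.707 adjusted). Of their genes 0 were called over all genes or adjusted over the list alone. Neither passed with a term for the low-rRNA set (adjusted p = 0.893 and 0.158). The microglia list was also lost without WT ZT18 replicate 3 or 4 or KO ZT18 replicate 2 or 4 (adjusted p = 0.0851, 0.765, 0.0888 and 0.0621). The mural list was lost without WT ZT18 replicate 3 (adjusted p = 0.0894). The neuron median was 0.37 without WT ZT18 replicate 2 and 0.88 without replicate 4. edgeR called 488 genes, 318 higher and 170 lower, against 237 and 234 with RLE scaling and 198 and 259 with library size alone. With a term for the low-rRNA libraries, carried over to ZT18 from the other times, Mbp (1.80) and Snx33 (1.55) alone passed. Lars2 and CT010467.1 turned to 0.68 and 0.72 with it. Without the single-sex libraries Snx33 alone passed. The count was 254, 200, 55 and 65 without WT ZT18 replicates 1 to 4, 95, 132, 161 and 44 without KO ZT18 replicates 1 to 4, and 761 without KO ZT6 replicate 3.

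**Figure D3:**
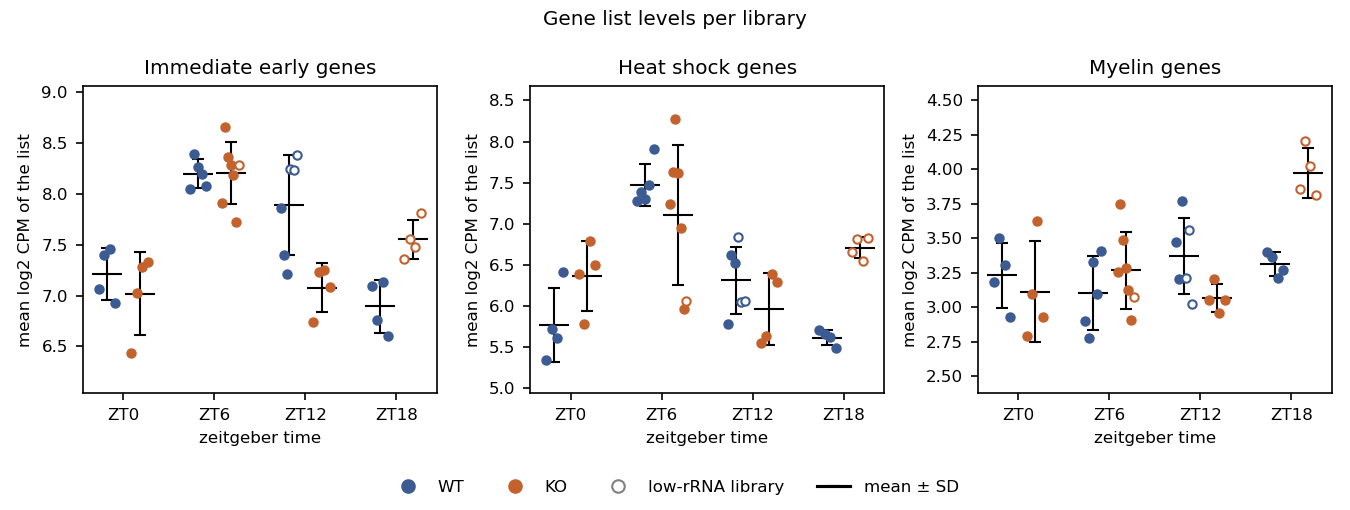
Mean log2 CPM (y axis) of the immediate early, heat shock and myelin gene lists in each library by zeitgeber time (x axis) and genotype, with points for libraries (open for the low-rRNA set) and bars for the mean ± SD. The myelin list was highest in KO at ZT18, at 3.97 ± 0.179 against 3.31 ± 0.087 in WT, and all 4 KO libraries there belonged to the low-rRNA set.

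Whether the genotype difference depended on the hour was tested by the interaction of genotype and time. The genes with the strongest interaction were lower in KO at ZT12 and higher at ZT18. The low-rRNA libraries lie in WT at ZT12 and in KO at ZT18, so genes higher in that set would show the same signs. Cebpb, an inducible transcription factor, had -1.76 (SE 0.329) and 1.83 (SE 0.347) at these times, Gnas, the stimulatory G protein subunit, -1.20 (SE 0.202) and 0.85 (SE 0.213), and the microtubule kinase Mark4 -0.63 (SE 0.091) and 0.39 (SE 0.0977). Their adjusted interaction p was 0.000198, 0.000198 and 0.00015. Immediate early genes were called more often than other genes (13 of 22, or 15 adjusted over the list alone; Fisher's exact test, one-sided, adjusted p = 2.47e-07), as were oxidative phosphorylation genes (8 of 24, or 12 adjusted over the list alone; adjusted p = 0.0164). Of the core clock genes 6 of 24 were called, or 10 adjusted over the list alone (adjusted p = 0.0921), with Dbp at 0.00198 and Clock at 0.0153. Fisher's test treats the genes of a list as independent, so its p-values here may be too small. The difference in Imp3 also depended on time (adjusted p = 0.0137), from 0.96 at ZT0 to 0.08 at ZT12, whereas Per3 did not pass (adjusted p = 0.0929). edgeR called 2096 genes for the interaction, with 3175 without WT ZT0 replicate 4 and 1049 without KO ZT12 replicate 1. With a term for the low-rRNA libraries 43 remained among the 2096, and without these libraries, where KO ZT18 could not be included, the count was 0, whereas DESeq2 called 3166 and limma-voom 5629 with all libraries, and 5633 had an unadjusted p under 0.05.

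WT cells collected at ZT6 showed a surge of inducible genes. The cells of each time were dissociated and panned before sequencing, and no sample separates an effect of that handling or of the collection from time of day. Atf3 was higher at ZT6 (1508 ± 211.5 CPM, SD, n = 5) than at ZT0 (243 ± 51.2 CPM, n = 4), ZT12 (690 ± 301 CPM, n = 6) and ZT18 (149 ± 49.6 CPM, n = 4), with adjusted p = 6.77e-08 for time. Maff, a small Maf factor, averaged 160 ± 24.1 CPM (SD, n = 5) at ZT6 and 16 ± 3.46 CPM (n = 4) at ZT18 (adjusted p = 7.25e-08), and Rel, an NF-kB subunit, 327 ± 84.7 and 41.7 ± 8.06 CPM (adjusted p = 9.3e-08). Of 22 immediate early genes 14 changed with time, 13 of them highest at ZT6, and 18 changed adjusted over the list alone (Fisher's exact test, one-sided, adjusted p = 3.31e-12). Of 16 heat shock genes 11 changed, all highest at ZT6, and 12 adjusted over the list alone (adjusted p = 2.27e-10). Hspa1a averaged 527 ± 376 CPM (n = 5) at ZT6 and 3.49 ± 0.692 CPM (n = 4) at ZT18. The clock genes Ciart and Per1, a repressor and a period gene, also peaked at ZT6, Ciart at 64.4 ± 6.08 CPM (n = 5) against 5.94 ± 0.75 CPM (n = 4) at ZT18 (adjusted p = 9.64e-07) and Per1 at 252 ± 64.9 against 48.8 ± 11.2 CPM (adjusted p = 1.83e-06). Of 24 core clock genes 7 changed, all highest at ZT6, and 8 adjusted over the list alone (adjusted p = 0.000545), and of 20 direct BMAL1 target genes 8 changed, and 10 adjusted over the list alone (adjusted p = 1.39e-05). Astrocyte markers also changed (11 of 18, or 13 adjusted over the list alone; adjusted p = 1.01e-09) with none highest at ZT6, and Gfap, a filament protein of astrocytes, averaged 15.4 ± 6.96 CPM (n = 5) at ZT6 and 56.2 ± 22.6 CPM (n = 4) at ZT18 (adjusted p = 0.00828). Neuron markers changed in 5 of 20 cases (8 adjusted over the list alone; adjusted p = 0.00671) and red blood cell markers in 6 of 9 (6 adjusted over the list alone; adjusted p = 6.97e-06), while OPC, microglia and endothelial markers had 0 called by edgeR over all genes or adjusted over the list alone. The Fisher p-values of these lists treat their genes as independent and may be too small. edgeR called 1120 genes, of which 698, or 62.3%, were highest at ZT6. The count was 724 without the 8 low-rRNA libraries, 487 without the single-sex libraries and 661 without WT ZT6 replicate 2.

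**Figure D4:**
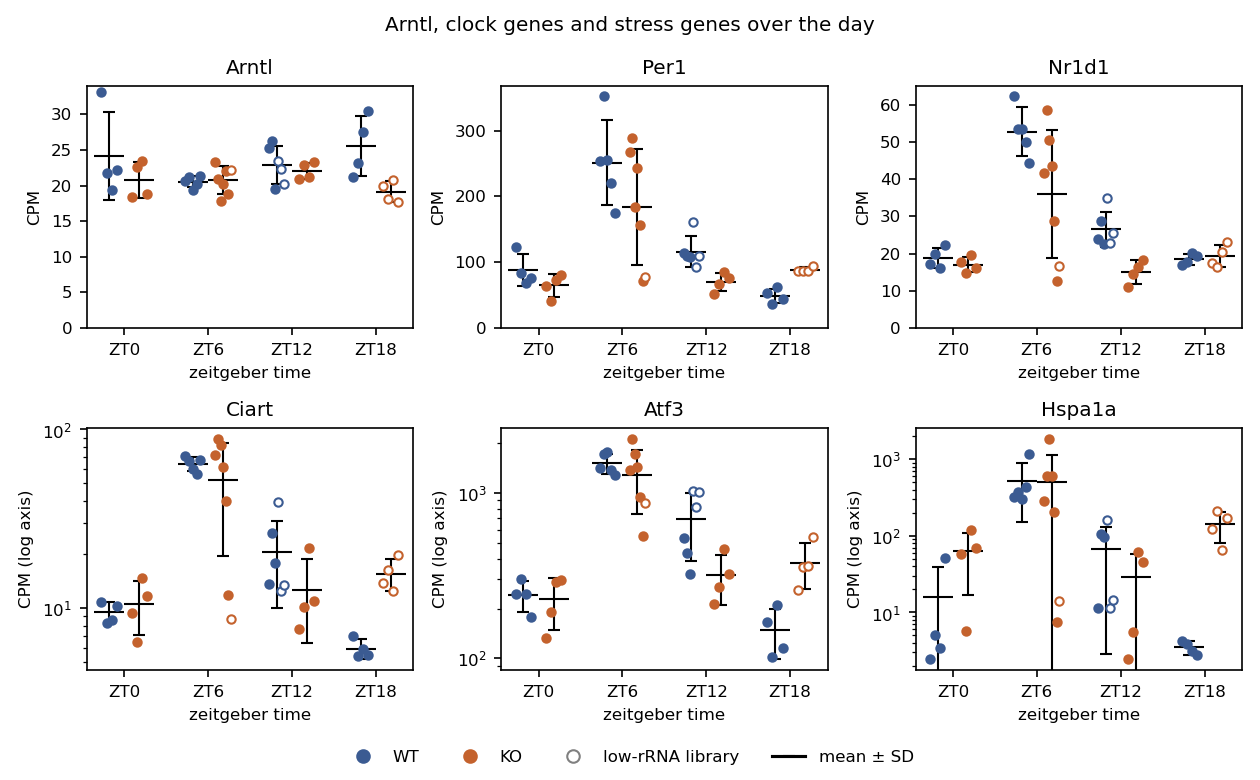
CPM of 6 genes (y axis; log axis for Ciart, Atf3 and Hspa1a) in each library by zeitgeber time (x axis) and genotype, with points for libraries (open for the low-rRNA set) and bars for the mean ± SD. Per1 was highest at ZT6 in WT, at 252 ± 64.9 CPM, and Hspa1a in KO at ZT18 averaged 143 ± 61.6 CPM against 3.49 ± 0.692 CPM in WT.

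In KO cells a ZT6 surge of immediate early genes was also present. Maff averaged 129 ± 60.3 CPM (SD, n = 7) at ZT6 and 26.4 ± 8.5 CPM (n = 4) at ZT12 (adjusted p = 4.19e-06). Irf4, an interferon regulatory factor, averaged 21.6 ± 9.57 CPM (n = 7) at ZT6 and 4.35 ± 2.07 CPM (n = 4) at ZT0 (adjusted p = 3.31e-06), and Bag3, a cochaperone of HSP70, 69.4 ± 48.3 and 13.6 ± 3.69 CPM (adjusted p = 4.19e-06). All 22 immediate early genes changed, over all genes and adjusted over the list alone, with 19 highest at ZT6 (Fisher's exact test, one-sided, adjusted p = 1.05e-13). Of 16 heat shock genes 12 changed, 10 of them highest at ZT6, and 14 adjusted over the list alone (adjusted p = 7.72e-05). Their mean log2 CPM at ZT6 was 5.96 and 6.06 in KO replicates 6 and 7 and from 6.95 to 8.28 in the other 5, against means of 6.37 at ZT0 and 6.71 at ZT18, so 2 of the 7 libraries showed no heat shock surge. Of 24 cholesterol biosynthesis genes 14 changed, none highest at ZT6, and 18 adjusted over the list alone (adjusted p = 0.000675). Per1 averaged 184 ± 87.8 CPM (n = 7) at ZT6 and 65.0 ± 17.8 CPM (n = 4) at ZT0 (adjusted p = 0.000118), and 12 of 24 core clock genes changed, or 16 adjusted over the list alone (adjusted p = 0.00703). Markers of other cells changed as well, with 15 of 20 neuron markers (19 adjusted over the list alone; adjusted p = 1.08e-05), 9 of 9 red blood cell markers (9 adjusted over the list alone; adjusted p = 1.33e-05) and 11 of 20 microglia markers (13 adjusted over the list alone; adjusted p = 0.00542). As in WT, the Fisher p-values treat the genes of a list as independent and may be too small. Of the genes called in WT, 841 were also called in KO, where 246 would be shared by chance, and 578 of these had the same peak time. edgeR called 5001 genes in KO, with the peak at ZT18 for 1895. The count was 2050 without the 8 low-rRNA libraries, which leaves no ZT18 library, 2656 with a term for them and 134 with surrogate variables.

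A 24 h cosine was fitted to each of the 24 core clock genes to compare rhythms. With 4 times, a fitted peak can rest on 1 collection time, and handling at that time is not separated from a rhythm. In WT 7 genes were rhythmic, all with a fitted peak between ZT5.64 and ZT7.53, led by Ciart with a log2 amplitude of 1.83 (SE 0.259, adjusted p = 1.65e-06), Per1 with 1.21 (SE 0.172, adjusted p = 1.65e-06) and Nfil3 with 1.08 (SE 0.173, adjusted p = 1.08e-05). These peaks lie near ZT6, the time of the surge of inducible genes. In KO 13 were rhythmic, among them Ciart with an amplitude of 0.99 (SE 0.233, adjusted p = 0.00446) and Per1 with 0.61 (SE 0.158, adjusted p = 0.00808). KO ZT6 replicates 6 and 7 had core clock means of 4.78 and 4.71 log2 CPM, against 4.92 to 5.33 in the other KO ZT6 libraries. Without them 10 genes were rhythmic in KO. All KO ZT18 libraries belonged to the low-rRNA set. No gene passed for a difference in rhythm between genotypes. The lowest adjusted p was 0.0525, shared by Clock, Dbp and Bhlhe40, and Per1 had 0.107. edgeR called 0 differences where limma-voom called 12, and 10 genes had an unadjusted p under 0.05. Leaving out 1 library gave up to 5 differences: 5 without KO ZT6 replicate 2 or 3, 4 without WT ZT0 replicate 3, WT ZT12 replicate 1, KO ZT0 replicate 1 or 2 or KO ZT6 replicate 1, 3 without WT ZT0 replicate 4, KO ZT0 replicate 4 or KO ZT6 replicate 7, and 1 without KO ZT6 replicate 4. The rhythmic genes in KO numbered 8 without KO ZT6 replicate 1 or 4 and 0 with surrogate variables.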

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

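The tests of the chromosome 9 and chromosome 1 genes, the test of the myelin genes within WT ZT12, the comparison with BMAL1 loss at ZT18, and every fit that leaves out or corrects for the low-rRNA or single-sex libraries or corrects for GC content and length were chosen only after the result was seen.

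Single libraries stood far from the rest of their group in 5 of 96 groups of values, where chance gives about 1 in 20, or 4.8. WT ZT6 replicate 5 held 34.3 M counts against 21.6 to 24.2 M in the other WT ZT6 libraries. Mbp stood at 139 CPM in WT ZT12 replicate 3 against 66.8 to 91.4 CPM in the others of that group. Hspa1a, the inducible HSP70 chaperone, stood at 51.9 CPM in WT ZT0 replicate 4 against 2.46 to 5.01 CPM, at 1190 CPM in WT ZT6 replicate 5 against 308 to 438 CPM, and at 1850 CPM in KO ZT6 replicate 3 against 7.51 to 602 CPM. Apart from these values, KO ZT12 replicate 3 stood alone on the third principal component of all libraries (-156.7, against -30.744 or higher in the others). It also had the fewest genes detected (19699) and the lowest weight in limma-voom (0.242), and without it 259 instead of 1139 genes passed at ZT12.

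Among the genes with the smallest interaction p-values and the core clock genes, 16 had a KO minus WT difference that changed with time. The adjusted p of the interaction was 0.00015 for Mark4, Gpr137 and Rrp9, which acts in ribosomal RNA processing. It was 0.000167 for Pcsk1n, an inhibitor of prohormone convertase, and 0.000198 for Map7d1, Trim8, Cebpb, Gnas, Basp1 and Dexi. All 10 had a negative log2 fold change at ZT12 and a positive one at ZT18, as for Rrp9 (-0.78 and 0.35), Pcsk1n (-1.02 and 0.52), Map7d1 (-0.69 and 0.61), Trim8 (-0.65 and 0.59), Basp1 (-0.56 and 0.57), Gpr137 (-0.56 and 0.43) and Dexi (-0.75 and 0.40). In the clock it was 0.00198 for Dbp, 0.0153 for Clock, 0.0277 for Per1, 0.0279 for Csnk1e, a clock kinase, 0.03 for Bhlhe41 and 0.0452 for its relative Bhlhe40. The low-rRNA set holds 3 of the 6 WT ZT12 libraries and all 4 KO ZT18 libraries. Genes higher in that set would show the same signs as the 10 above, so set and genotype cannot be told apart here. Of the 2096 interaction calls 43 remained with a term for the set. Without its libraries, and so without KO ZT18, the count was 0.

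Snx33 and Imp3 lie next to Cspg4 on chromosome 9, and Tagln2, Cadm3 and Mndal lie within a stretch of chromosome 1 that holds the Ifi200 family. Extra copies of this region carried with a Cspg4-based Cre transgene cannot be told apart. The 5 genes within 150 kb of Cspg4 that did not pass themselves, Cspg4 included, had a mean signed z of 0.723, reached by 11.4% of 22703 runs of neighbouring genes. With Gm47237, which passed, in place of Cspg4 the share was 0.0837%, so the outcome turned on the choice of genes. Lingo1 at one end had a log2 fold change of 0.00 (SE 0.0672), Ptpn9 at the other 0.08 (SE 0.0431), and Snupn before it 0.02 (SE 0.0775), and how far any copies reach is unknown. On chromosome 1, 7 of 30 tested genes in 2 Mb had a p under 0.001, 4 higher and 3 lower in KO (permutation p = 0.002), which may reflect the transgene insertion site or DNA of another strain linked to it. Loss of BMAL1 as the cause cannot be told apart, since no Cre-positive group with intact Bmal1 exists. The difference in Snx33 did not pass for dependence on time (adjusted p = 0.393), whereas that in Imp3 did (adjusted p = 0.0137), from 0.96 at ZT0 to 0.08 at ZT12. A difference between mouse substrains at these loci stays open as untested.

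At ZT12 1139 genes were called, yet few of the calls survived corrections. A term for the low-rRNA set, which holds 3 of the 6 WT ZT12 libraries, left the fold changes on a slope of 0.94 with all 1139 signs the same, while the median size went from 0.517 to 0.428 and its SE from 0.131 to 0.141, so that 77 calls were kept. With the GC and length correction the slope was 0.898 and 1068 signs were the same, while the median size went from 0.517 to 0.245 and its SE from 0.131 to 0.115, so that 81 calls were kept. Leaving out 1 ZT12 library gave a lowest slope of 0.936, for KO ZT12 replicate 3, where 245 calls were kept. The slopes stayed at 0.898 or higher, but a slope weighs the largest folds most. The GC and length correction lowered the median size to 0.245 and took the calls from 298 higher and 841 lower to 60 and 62. For a typical called gene, much of the difference thus went with GC content and length. Too few calls were kept for any of these 3 to be ruled out as a part of the ZT12 count. An effect of BMAL1 cannot be told apart from them for genes that lost their call.

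At ZT18 the myelin list was higher in KO by 0.66 (SE 0.0994), and all 4 KO libraries but 0 of the WT libraries there belonged to the low-rRNA set. Within WT ZT12 the list differed by -0.216 (SE 0.226) between low-rRNA and other libraries, below 0.331, which is 0.5 times the ZT18 difference. That direction goes against the low-rRNA set as the cause. With 3 low-rRNA libraries among 6, and the highest library (replicate 3, at 3.77) among the others, this check is too small to exclude the set. KO ZT6 holds 1 low-rRNA library, too few for a second check. A lower share of OPCs in these KO libraries stays open and cannot be told apart: all 7 lists of other cell types were higher, from 0.11 for astrocyte to 1.00 for choroid plexus markers, while OPC markers differed by -0.13. The median of the astrocyte markers flipped from 0.035 to -0.00376 with RLE scaling and to -0.0402 with library size alone, where all genes shifted alike by -0.0359 and -0.0639, so the flip does not bear on astrocytes relative to the other lists. Only 1 of these lists, that of astrocytes, lay more than 2 standard errors from their median, and its high level of 6.75 log2 CPM in WT would hide a small share. Loss of BMAL1 likewise stays open, with Mbp at 1.25 (SE 0.231) and at 1.80 (SE 0.29) with a term for the set. The larger value is no correction for the set, since the term was estimated within WT ZT12 and KO ZT6. In WT ZT12 the highest Mbp value lay outside the set, at 139 CPM in replicate 3.

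Other splits of the same libraries into groups of the same sizes were fitted to see whether chance, but not an uneven set of libraries, can be excluded. It can be excluded for the 21 genes over all times (2 of 100 splits gave as many, highest other 334), the 3 genes at ZT6 (4 of 100, highest other 1488) and the 1139 genes at ZT12 (1 of 100, highest other 728). It can also be excluded for the 488 genes at ZT18 (1 of 35, highest other 2), the 2096 genes of the interaction (1 of 100, highest other 366), and the 1120 and 5001 genes that changed with time in WT and KO (1 of 100 each, highest other 482 and 1550). It cannot be excluded for the 65 genes at ZT0, where 3 of 35 splits gave as many and the highest other gave 1689. Splits with several times the real count point to a structure of the samples: the highest at ZT0 set WT ZT0 replicates 1, 2 and 3 with KO ZT0 replicate 4 against the rest, and the highest at ZT6 set WT ZT6 replicates 1 to 4 with KO ZT6 replicates 1, 2 and 4 against the rest. With such a structure the libraries are not interchangeable, so the exclusions at ZT6 and over all times are weak. The highest other split at ZT12 set WT ZT12 replicates 1, 4, 5 and 6 against the rest. It kept the low-rRNA libraries of that time together, but so did the split that joined them with KO ZT12 replicate 4, which gave 0 genes. At ZT18 only the real split set the low-rRNA libraries against the others, so this test cannot tell genotype from that set. The set is also uneven between the groups at ZT12, in the interaction and over the times in KO, and these splits do not correct for it.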

How the results depend on the processing

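The fits without the 8 low-rRNA libraries, with a term for them, with the GC and length correction, without KO ZT6 replicates 6 and 7 and without single-sex libraries were chosen after seeing the data. Of 56 named results of single genes, 50 kept direction and side of the threshold with RLE scaling, 48 with library size alone, 55 with the stricter filter, 49 without a filter, 56 with DESeq2, 45 with limma-voom, 27 with surrogate variables, 37 with the covariate for male RNA, 49 with the replicate block, 20 of 41 with only the samples compared and 9 of 15 with the additive model. The count was 11 of 43 without the 8 low-rRNA libraries, 25 with a term for them (2 reversed), 27 with the GC and length correction, 43 without KO ZT6 replicates 6 and 7 and 15 without single-sex libraries. Over the fits that left out 1 library it was 1632 of 2128. Snx33, Imp3, Tagln2, Per3 and Nr1d2 over all times passed under every setting run. CT010467.1 and Lars2 at ZT18 reversed to 0.72 and 0.68 with the term for the low-rRNA set. Counting noise, which depth sets, gave a median of 10.1% of the variance within groups and under 50% for 22773 of 22798 genes, and simulated data at other depths were not run. Of 72 list calls 45 were kept in every fit that left out 1 library. Where values below differ from those reported, the cause was not tested, apart from fits with fewer libraries.

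With DESeq2 the calls numbered 244 over all times, 1018 at ZT0, 1211 at ZT18, 3166 for the interaction and 1778 for time in WT. With limma-voom they numbered 1056, 2364, 5 at ZT6, 4135 at ZT18, 5629 for the interaction and 4281 for time in WT, with 12 rhythmic clock genes in WT and 12 rhythm differences. With surrogate variables they numbered 2 at ZT0, 190 at ZT12, 292 at ZT18, 243 for the interaction, 648 and 134 for time in WT and KO, 33 lists at the single times, 0 rhythmic genes in KO and 4 differences. The stricter filter gave 169 at ZT0. The covariate for male RNA gave 15 at ZT0, 207 at ZT18 and 1 rhythm difference. The additive model gave 8 over all times, and the 24 h cosine 1575 for time in KO. Fits of only the samples compared gave 1 at ZT0, 1 at ZT6, 145 at ZT12 and 2393 at ZT18. Camera with an estimated correlation called 0 lists over all times and 0 at single times, and fry 6 and 21.

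Without the 8 low-rRNA libraries the calls numbered 5 over all times, 4 at ZT0, 1 at ZT6, 1 at ZT12, 0 for the interaction, 724 and 2050 for time in WT and KO, and 9 and 30 lists. No value exists at ZT18, so over all times means ZT0, ZT6 and ZT12 in this fit. With a term for them they numbered 8, 115 at ZT0, 78 at ZT12, 2 at ZT18, 43 for the interaction and 2656 for time in KO. The GC and length correction gave 10 at ZT0, 122 at ZT12, 101 at ZT18 and 453 for the interaction. Without KO ZT6 replicates 6 and 7 they numbered 13 over all times, 13 at ZT0 and 1 at ZT6. Without single-sex libraries they numbered 8 over all times, 1 at ZT0, 1 at ZT6, 712 at ZT12, 1 at ZT18, 724 for the interaction, 487 and 3034 for time in WT and KO, and 7 rhythmic genes in KO.

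The sample numbers may or may not pair libraries, so a replicate block was tried: it gave 467 at ZT0, 726 at ZT12, 996 at ZT18 and 1 rhythm difference. Across 17 pairs of libraries with the same number, the mean correlation of residuals was 0.02 against -0.00262 for other numbers, 2 pairs exceeded 0.1, and 3 libraries correlated best with their own number.

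Leaving out each library in turn gave 10 to 633 genes over all times, 1 to 2208 at ZT0, 2 to 5 at ZT6, 259 to 1357 at ZT12, 44 to 761 at ZT18, 1049 to 3175 for the interaction, 661 to 1449 for time in WT and 3632 to 5301 in KO. Lists numbered 14 to 19 and 54 to 63, rhythmic clock genes 6 to 8 in WT and 8 to 14 in KO, and rhythm differences 0 to 5. The libraries behind each shift are named with the results.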

Other observations

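The list tests without or with a term for the low-rRNA or single-sex libraries were chosen after the result was seen, while the other tests of gene lists were planned.

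The combined Notch, BMP and Wnt list, the matrix list and the unfolded protein list were lower in KO at ZT12, with few of their genes called. Of 22 genes of the Notch, BMP and Wnt response 21 were negative (median -0.28), and 3 fell, over all genes and adjusted over the list alone (list adjusted p = 0.00216, p = 0.0348 with an estimated correlation, 0.368 adjusted). Smad7, an inhibitor of TGF-beta and BMP signalling, stood at 0.498 of its WT level (SE of log2 0.223, adjusted p = 0.00772). Of 25 extracellular matrix and integrin genes 21 were negative (median -0.35), with 4 lower over all genes and 10 adjusted over the list alone (list adjusted p = 0.00199, p = 0.119 with an estimated correlation, 0.538 adjusted), and the collagen gene Col5a1 had -1.01 (SE 0.224, adjusted p = 0.00786). Of 18 genes of the unfolded protein response 16 were negative (median -0.15), with 2 lower over all genes and 2 adjusted over the list alone (list adjusted p = 0.0122, p = 0.208 with an estimated correlation, 0.653 adjusted), and Atf4, its translation-controlled factor, had -0.82 (SE 0.159, adjusted p = 0.00303). At ZT18 this list was higher (16 of 18 positive, median 0.17, list adjusted p = 0.0156, p = 0.223 with an estimated correlation, 0.66 adjusted), with 1 called over all genes and 1 adjusted over the list alone. It did not pass there with a term for the low-rRNA set (median -0.02, adjusted p = 0.996) or without WT ZT18 replicate 4 or KO ZT18 replicate 4 (adjusted p = 0.0744 and 0.0515). At ZT12 19 of 24 genes of G2/M and mitosis were positive (median 0.18), with 1 called over all genes and 1 adjusted over the list alone (list adjusted p = 0.00101, p = 0.252 with an estimated correlation, 0.707 adjusted). Without the 8 low-rRNA libraries the Notch, BMP and Wnt and the G2/M lists passed (adjusted p = 0.0279 and 9.84e-07), whereas the matrix and unfolded protein lists did not (adjusted p = 0.114 and 0.677). The G2/M list did not pass without the single-sex libraries (adjusted p = 0.0823), nor the unfolded protein list without KO ZT12 replicate 4 (adjusted p = 0.0717). Without WT ZT12 replicate 5 the medians of the Notch and matrix lists were -0.155 and -0.174, and without KO ZT12 replicate 3 those of the G2/M and unfolded protein lists 0.115 and -0.231.

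Cholesterol biosynthesis genes were lower at ZT12 (23 of 24 negative, median -0.23, list adjusted p = 0.00261, p = 0.273 with an estimated correlation, 0.729 adjusted), with 2 called over all genes and 6 adjusted over the list alone. This list did not pass without KO ZT12 replicate 2 (adjusted p = 0.0553) or without the single-sex libraries (adjusted p = 0.773). At ZT18 all 24 were positive (median 0.28, list adjusted p = 1.77e-06, p = 0.094 with an estimated correlation, 0.496 adjusted), with 0 called over all genes and 4 adjusted over the list alone. At that time ion channels and transmitter receptors were lower (20 of 24 negative, median -0.24, list adjusted p = 3.83e-05, p = 0.134 with an estimated correlation, 0.551 adjusted), with 0 called over all genes and 7 adjusted over the list alone. Antioxidant genes (17 of 20 positive, median 0.26, list adjusted p = 0.000102) and glucocorticoid targets (13 of 17, median 0.42, list adjusted p = 0.00194) were higher, with p = 0.0268 and 0.032 with an estimated correlation (0.368 each adjusted). Of these, 0 were called over all genes, and 5 and 8 adjusted over the list alone. With a term for the low-rRNA set the cholesterol, antioxidant and glucocorticoid lists passed (adjusted p = 7.98e-11, 0.00544 and 0.00544), whereas the ion channel list did not (adjusted p = 0.0901). That term cannot separate the set from genotype at ZT18. At ZT12 glucocorticoid targets were lower (15 of 17 negative, median -0.36, list adjusted p = 0.0143, p = 0.0824 with an estimated correlation, 0.491 adjusted), with 1 called over all genes and 2 adjusted over the list alone, but not without the 8 low-rRNA libraries (adjusted p = 0.0667). At ZT18 Gadd45b, a growth arrest gene, rose by 2.88 (SE 0.64, adjusted p = 0.0182). In WT, glucocorticoid targets changed with time of day in 9 of 17 cases (9 adjusted over the list alone; Fisher's exact test, one-sided, adjusted p = 2.33e-07), 8 of them highest at ZT6. Genes of the unfolded protein response changed in 6 of 18 cases (7 adjusted over the list alone; adjusted p = 0.000657), all 6 highest at ZT6.

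Choroid plexus and ependymal markers were higher in KO over all times (11 of 12 positive, median 0.59, list adjusted p = 0.000344, p = 0.0211 with an estimated correlation, 0.141 adjusted), with 0 called over all genes and 3 adjusted over the list alone. They did not pass without the 8 low-rRNA libraries, a fit that leaves out ZT18 (median 0.51, adjusted p = 0.0547). At ZT18 their median was 0.99 (list adjusted p = 0.00781, p = 0.0605 with an estimated correlation, 0.433 adjusted), with 0 called over all genes and 2 adjusted over the list alone. In WT 0 of 19 mural and fibroblast markers changed with time over all genes and 7 adjusted over the list alone, and none of the 6 sex-linked genes was called over all times (list adjusted p = 0.153). The labels state 2 pooled mice per library and both sexes, whereas in the 7 libraries with female RNA alone Y-linked genes stood at 0 CPM, against 69.4 CPM or more in the others. In the 6 libraries with male RNA alone Xist reached at most 12.4 CPM, against 966 CPM or more in the others.

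The remaining lists that passed camera at the preset correlation, none of which passed with an estimated correlation after adjustment, were as follows. Over all times they were higher for G1/S (adjusted p = 0.00446), G2/M (0.00288), actin (0.000297), cholesterol (4.01e-05), glycolysis (8.72e-05), antioxidant (4.9e-05), heat shock (0.00771) and autophagy genes (0.0118). At ZT0 they were higher for fatty acid synthesis (0.0272), glycolysis (0.0217), antioxidant (0.000248), heat shock (0.00261) and ribosomal protein genes (3.42e-07). At ZT6 G1/S (0.022), oxidative phosphorylation (3.05e-06), glycolysis (0.0099), interferon (0.0308) and ribosomal protein genes (5.59e-06) were higher and ion channels lower (0.0206). At ZT12 the core clock was lower (0.0189), and at ZT18 G2/M (0.0319), cell cycle inhibitor (0.0179), actin (0.000218), oxidative phosphorylation (8.52e-10) and autophagy genes (0.000339) were higher. Leaving out 1 library ended some of these calls. That of autophagy over all times was lost without WT ZT0 replicate 1, WT ZT18 replicate 4 or KO ZT12 replicate 3 (adjusted p up to 0.0751). At ZT0 fatty acid synthesis was lost without WT replicate 1 or 3 or KO replicate 1 (up to 0.118), glycolysis without WT replicate 1 or KO replicate 3 (up to 0.141) and heat shock without WT replicate 1 (0.053). At ZT6 G1/S was lost without WT replicate 1 or KO replicate 3, 5 or 7 (up to 0.235), glycolysis and ribosomal proteins without KO replicate 3 (0.0562 and 0.0866), interferon without WT replicate 3, 4 or 5 or KO replicate 2, 3 or 7 (up to 0.234), and ion channels without WT replicate 1 or 4 or KO replicate 2, 3, 5 or 7 (up to 0.28). At ZT12 the core clock was lost without KO replicate 2 or 4 (up to 0.0544). At ZT18 G2/M was lost without WT replicate 4 or KO replicate 1 or 2 (up to 0.539) and cell cycle inhibitors without WT replicate 4 (0.0819). Without the 8 low-rRNA libraries, actin, cholesterol, glycolysis, heat shock and autophagy genes over all times (adjusted p = 0.0614, 0.223, 0.243, 0.173 and 0.218) and G1/S, interferon and ion channels at ZT6 (0.232, 0.0591 and 0.0691) did not pass. With a term for this set G1/S over all times (0.227), G1/S, interferon and ion channels at ZT6 (0.203, 0.0714 and 0.0621) and G2/M, cell cycle inhibitors and autophagy at ZT18 (0.683, 0.38 and 0.0579) did not pass. The ZT18 G2/M test pointed down there. Without the single-sex libraries G1/S and G2/M over all times (0.0795 and 0.228), fatty acid synthesis at ZT0 (0.2), the core clock at ZT12 (0.211) and G2/M at ZT18 (0.767) did not pass, nor did G1/S at ZT6 without KO ZT6 replicates 6 and 7 (0.471).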
